A study of Mus musculus with 21 samples.

How the data were processed

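RPA ChIP-seq was made in passage-immortalized mouse embryonic fibroblasts with 1 functional Atr copy, per the labels' protocols. There were 21 libraries, 13 of ChIP and 8 of input chromatin, in 6 treatment groups. ChIP used chromatin sheared to under 4 kb, an RPA32 antibody in 3 lots, and libraries of about 200 bp fragments amplified for 18 PCR cycles, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.17.1.14, STAR 2.5.2a, SAMtools 0.1.19, Picard 1.141 and MACS2 2.1.0 and the mm10 build, without stating the role or settings of each.

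The deposited files used here were 6 peak lists, 1 per treatment, in which the peak names record all ChIP libraries of a treatment set against all its inputs. The number at the end of that name differed between 4 and 2 of the lists, and its meaning is not stated in the labels. Per peak, the authors' lists give a score, the fold enrichment of ChIP over input at the summit (a ratio), the −log10 p-value and the −log10 q-value of the peak caller, and the summit position. In the deposited values the score was 10 times the −log10 p, without its decimals, for all 683 peaks, so it was not used further. All 6 lists were sorted by falling −log10 p. The threshold of each list is not stated, and the lowest −log10 p differed from list to list. Read depth per library was unknown, so no normalisation for depth could be made, and replicates could not be separated.

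Gene positions came from a table of RefSeq genes on GRCm38.p6, which has the coordinates of mm10. Of 49997 entries, 49554 lay on chromosomes 1 to 19 and X, 340 entries on scaffolds were left out, and 49214 were used, of which 21523 were protein-coding. The table holds gene bodies without exons, and no genome sequence was at hand. The planned tests of tandem repeats, repeat units, inverted repeats, G-quadruplex motifs, GC content, exons, introns and transcription starts were therefore not run. The nearest gene body replaced the nearest transcription start for naming intergenic peaks. Coordinates are 1-based.

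The main tests, the gene lists, the naming rule and a set of alternatives were chosen before the data were examined. Two-sided permutation tests placed each peak of a list at random on its own chromosome 10000 times, between 3 Mb and the last annotated or listed base, over 2571 Mb in all; assembly gaps inside that span could not be left out. The same placements served overlap with another list by at least 1 bp (30 ordered pairs), summits within genes (12 tests) and summits within 7 gene lists for lists of at least 20 peaks (35 tests). Shares of peaks overlapping the ATRi+APH 18 h list were compared by Fisher's exact test, two-sided, over peaks (10 comparisons). Peaks per chromosome were tested by a chi-square statistic against 10000 draws in proportion to chromosome length. Median folds within the ATRi+APH 18 h list were compared by two-sided permutation tests with 100000 resamples (5 comparisons). P-values were adjusted by Benjamini-Hochberg within each family, with a threshold of 0.05. Intervals are exact Clopper-Pearson at 95%.

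Peaks named are the 10 of highest fold of each list (all for a list of 10 or fewer), the genes at the 25 of highest fold in the ATRi+APH 18 h and ATRi+shTIM lists, loci present in at least 4 lists (the 10 of highest fold in ATRi+APH 18 h) and genes of the fixed lists that held a peak. Intergenic peaks are named by the nearest protein-coding gene. Predicted genes known only by Gm or Rik numbers were counted and not named, and 2 further loci that the rule names are not reported here. Names outside this rule are said in the text to have been chosen after their values were seen.

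Alternatives fixed beforehand, each for some of the results, were peaks at or above the pooled median fold of 9.83, a −log10 q of at least 10, merging within 1 kb, 50% coverage or 1 kb distance for overlap, removal of peaks overlapping DMSO, protein-coding genes only, placement anywhere in the genome, and peaks under 1 Mb apart counted once. Alternatives chosen after seeing the data were a common −log10 p of at least 34, shifting a whole list along each chromosome, merging in tests for which it had not been planned, removal of peaks overlapping DMSO for gene lists, folds and protein-coding shares, placement anywhere for protein-coding shares, and 50% coverage or 1 kb distance for folds. Leaving out a replicate was not possible with pooled lists.

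The statistics were tested on simulated data in 1000 simulations each. With no effect, p fell under 0.05 in 4% of simulated lists of 188 peaks for lying within 500 kb of a peak of another list, a distance used because random lists hardly ever overlap by 1 bp, so the rate for overlap by 1 bp itself was not measured. It did so in 4.5% of lists of 327 peaks for genes over 300 kb, 5.8% for shuffled folds and 5.8% for random chromosomes. The simulated lists treated peaks as independent, as the tests do, so these rates do not cover the clusters of neighbouring peaks in the real lists. A planted overlap of 50% was found in 100% of simulations with a largest error of 1.06 points, a shift of 60% of the peaks in long genes out of them in 100%, and folds of 65 peaks raised 1.5 times in 99.8%. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.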

Results

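The study mapped the single-stranded DNA binding protein RPA on chromatin of mouse embryonic fibroblasts. The cells were immortalized by passaging and carried 1 functional copy of Atr, which encodes the checkpoint kinase that stabilises stalled replication forks. Chromatin was precipitated with an antibody against RPA32, a subunit of RPA that coats the DNA exposed when forks stall or collapse. The treatments were DMSO for 18 h, aphidicolin (APH, an inhibitor of replicative DNA polymerases, 0.2 µM) for 18 h, an ATR inhibitor (ATRi, 1 µM) for 18 h, both drugs for 9 h or for 18 h, and the ATR inhibitor for 18 h in cells with short hairpin knockdown of Timeless (shTIM), a component of the fork protection complex. The libraries comprised 13 ChIP and 8 input libraries, with 2 ChIP libraries per condition except for 3 for ATRi+APH at 18 h. The deposited files were 6 peak lists, 1 per condition, each made from all ChIP and input libraries of its condition, so no list held a value per replicate and no spread between replicates could be computed. Library depth was unknown, and the tests below compared the lists, not the conditions over cultures. Exact confidence intervals cover counting error over peaks only.

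The 6 lists held 683 peaks. Each list ended at its own level of significance, so absence from a list was not absence of signal. The lowest −log10 p in a list was 10 for DMSO, 10.7 for ATRi+shTIM, 21.7 for ATRi+APH 18 h, 29.9 for ATRi, 34 for ATRi+APH 9 h and 39.5 for APH. Fold enrichment values are those of the authors' peak caller and describe peaks within their own list.

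The first question was which sites appeared without ATR inhibition. The DMSO list held 46 peaks covering 5.34 kb in all, with a median width of 95.5 bp and no peak wider than 292 bp. Its strongest peak, at 8.17-fold, lay on chromosome 2 from 124891238 to 124891317, and the nearest protein-coding gene was Slc24a5, 176847 bp away. The next, at 7.18-fold, lay 7863 bp from Trib1 on chromosome 15. Of the 10 strongest DMSO peaks, 7 were intergenic and 1 lay in a protein-coding gene, Elf2, which encodes an ETS-family transcription factor (chromosome 3, 51331691 to 51331783, 6.6-fold). None of these 10 overlapped a peak of another list. A group of 11 DMSO peaks stood at the start of the assembled part of chromosome 9, between 3000863 and 3038240, with folds of 1.92 to 2.77. The APH list held 1 peak, of 3.8-fold, in the same stretch (chromosome 9, 3002078 to 3002335), which overlapped a DMSO peak and an ATRi+APH 18 h peak. Aphidicolin alone therefore gave no listed peak outside a region also listed with DMSO.

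**Figure D1:**
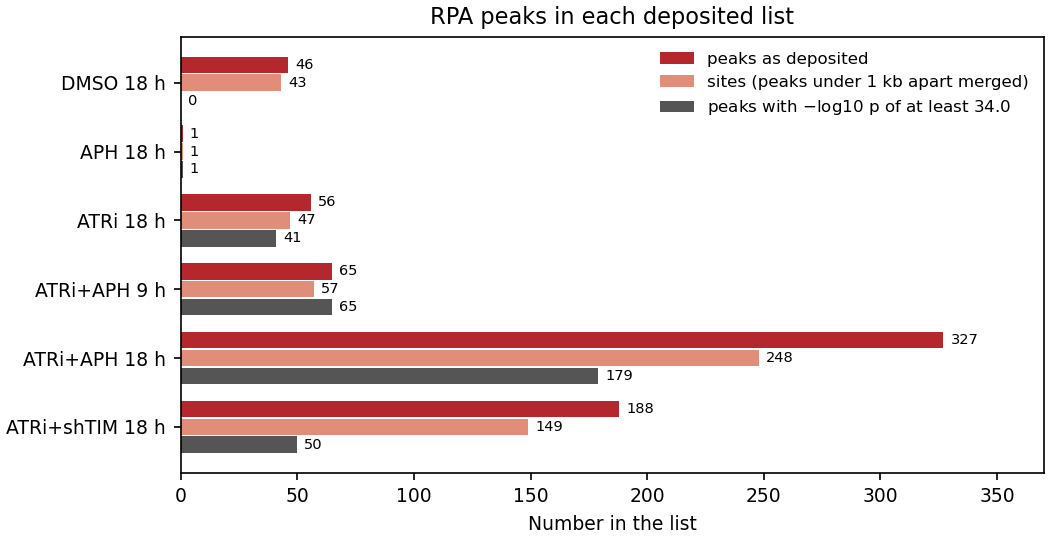
Horizontal bars give the number of entries (x axis) in each of the 6 deposited lists (y axis): peaks as deposited, sites after merging peaks under 1 kb apart, and peaks whose −log10 p reached 34, the floor of the ATRi+APH 9 h list. The ATRi+APH 18 h list was the longest by each count, with 327, 248 and 179 entries.

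ATR inhibition alone was compared with DMSO. The ATRi list held 56 peaks covering 41.4 kb, with 18 peaks wider than 1 kb and a widest peak of 2494 bp. The strongest lay near Gata4, a transcription factor of heart and endoderm (chromosome 14, 63278003 to 63280364, 15.9-fold), near Rnf145, which encodes an E3 ubiquitin ligase (chromosome 11, 44501477 to 44503705, 15-fold), and near Gdf3, a ligand of the TGF-beta family (chromosome 6, 122615996 to 122618489, 14.7-fold). Among the 10 strongest were also peaks inside the scavenger receptor gene Cd163l1 (chromosome 7, 140221247 to 140221436, 14.1-fold) and inside Polg, which encodes the mitochondrial DNA polymerase and whose peak also covered the tRNA gene n-TRtcg5 (chromosome 7, 79466126 to 79467270, 13.3-fold). Only 3 of the 56 ATRi peaks overlapped the DMSO list (5.36%, 95% interval 1.12 to 14.9%), more than the 0.0006 peaks expected from random placement (two-sided permutation p = 0.0002, the smallest that 10000 placements can give).

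Aphidicolin added to the ATR inhibitor was compared with each drug alone. The ATRi+APH 18 h list held 327 peaks covering 218 kb, with 66 peaks wider than 1 kb and a widest peak of 6317 bp. Its strongest peaks lay near Gdf3 (chromosome 6, 122616002 to 122622318, 51.6-fold), near Gata4 (chromosome 14, 63277107 to 63280371, 50-fold), near Klf15, a zinc finger transcription factor (chromosome 6, 90518716 to 90522651, 42.4-fold), inside Urgcp, a regulator of cell proliferation (chromosome 11, 5740330 to 5743870, 42.3-fold), and near Ptgr2, a prostaglandin reductase (chromosome 12, 84280555 to 84282846, 39.4-fold). Of its 25 strongest peaks 18 were intergenic and 2 lay in protein-coding genes, 20 were wider than 1 kb, and 22 overlapped at least 1 other list. Further named loci among them lay near Rnf145, Cd24a, Gp9 and Slit3, inside Cldn34-ps on chromosome X, and at larger distances from Spon1 (62236 bp) and Fam136a (33714 bp). Of the ATRi peaks, 54 of 56 overlapped this list (96.4%, 95% interval 87.7 to 99.6%), against 0.0102 expected from random placement (adjusted permutation p = 0.000286). The 2 exceptions, named after their values were seen, lay in the immediate early gene Egr1 (chromosome 18, 34861030 to 34861890, 10.1-fold) and at the tRNA gene n-TQctg6 (chromosome 11, 69124070 to 69124890, 10.4-fold). In the other direction 54 of the 327 peaks (16.5%) overlapped the ATRi list. Of the DMSO peaks, 9 of 46 overlapped the ATRi+APH 18 h list (19.6%, 95% interval 9.36 to 33.9%), a lower share than that of ATRi peaks (Fisher's exact test over peaks, adjusted p = 3.6e-16). That difference no longer passed the test among peaks with a −log10 q of at least 10 (adjusted Fisher's exact p = 0.153), where 5 DMSO peaks were left and 60% of them overlapped the ATRi+APH 18 h list. The counts themselves carry no test, and among peaks with a −log10 p of at least 34 they were 179 for ATRi+APH 18 h, 41 for ATRi and 0 for DMSO.

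**Figure D2:**
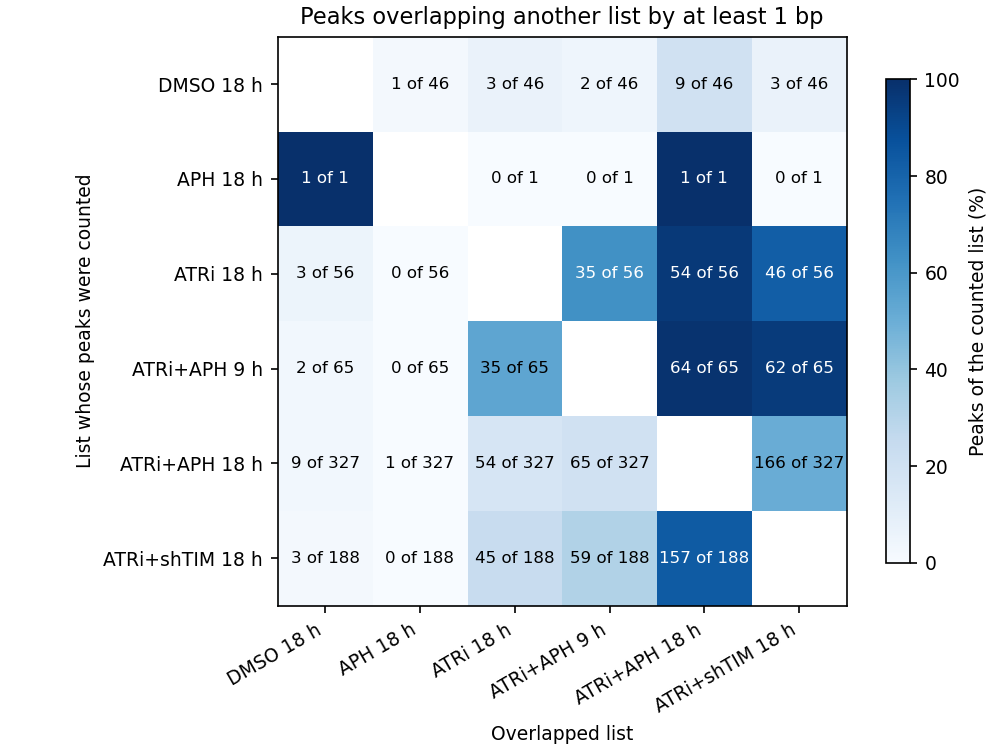
Each cell gives the number of peaks of the list on the y axis that overlapped the list on the x axis by at least 1 bp, and its colour gives that number as a percentage of the counted list. ATRi and ATRi+APH 9 h peaks lay almost all within the ATRi+APH 18 h list (54 of 56 and 64 of 65), and 9 of 46 DMSO peaks did.

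The time course compared 9 h with 18 h of the combined treatment. The ATRi+APH 9 h list held 65 peaks covering 40.7 kb, of which 17 were wider than 1 kb. Its strongest peaks lay near the vomeronasal receptor gene Vmn1r66 (chromosome 7, 10285004 to 10285140, 48.4-fold), inside the tight junction gene Cldn18 (chromosome 9, 99705772 to 99705924, 41.4-fold), near Spon1 (chromosome 7, 113703688 to 113703839, 40.9-fold) and near Klf15 (chromosome 6, 90518726 to 90520908, 39.3-fold). Other strong peaks lay near Gata4 and Gdf3, inside Shisa6, which encodes an auxiliary subunit of AMPA receptors (33.1-fold), and inside Acaca, which encodes acetyl-CoA carboxylase (31.2-fold). Of the 65 peaks, 64 overlapped the 18 h list (98.5%, 95% interval 91.7 to 100%; adjusted permutation p = 0.000286). The exception, named after its value was seen, lay 2680 bp from the olfactory receptor gene Olfr323 and was also in the ATRi+shTIM list. At 18 h, 65 of 327 peaks (19.9%, 95% interval 15.7 to 24.6%) overlapped the 9 h list. The widest peak near Gdf3 spanned 3554 bp at 9 h and 6317 bp at 18 h from the same start. The 18 h list was made from 3 ChIP libraries and the 9 h list from 2.

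Timeless knockdown was compared with aphidicolin as the second stress on top of ATR inhibition. The ATRi+shTIM list held 188 peaks covering 94 kb, of which 22 were wider than 1 kb. Its strongest named peaks lay inside Cd163l1 (chromosome 7, 140221189 to 140221480, 47.1-fold), near Gp9, which encodes a platelet glycoprotein (chromosome 6, 87774537 to 87775342, 43.9-fold), inside Nkap (chromosome X, 37130452 to 37130683, 41-fold) and inside the C-type lectin gene Clec2e (chromosome 6, 129096028 to 129096354, 40.1-fold). Further peaks among the 25 strongest lay near Gdf3, Klf15, Spon1, Tekt4, Ccdc66, Dcbld1, Gata4, Rnf145, L1cam and Asmt and inside Shisa6 and Mup-ps1, and all 25 overlapped at least 1 other list. Of the 188 peaks, 157 overlapped the ATRi+APH 18 h list (83.5%, 95% interval 77.4 to 88.5%; 0.03 expected from random placement, adjusted permutation p = 0.000286), and 166 of the 327 ATRi+APH 18 h peaks (50.8%, 95% interval 45.2 to 56.3%) overlapped the ATRi+shTIM list. The share for ATRi+shTIM was lower than that for ATRi+APH 9 h (adjusted Fisher's exact p = 0.00211) and for ATRi (adjusted p = 0.026). With the counted lists held to the same −log10 p of at least 34, neither difference passed the test (adjusted Fisher's exact p = 1 for each), and the point estimate against ATRi changed sign. This threshold was chosen after seeing the data and left 50 ATRi+shTIM peaks. It was not applied to the overlapped ATRi+APH 18 h list, which kept its 327 peaks.

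Joined across lists, the peaks formed 385 loci, of which 348 were in at least 1 list with ATR inhibitor. A total of 31 loci were in all 4 lists with ATR inhibitor, 154 were in both the ATRi+APH 18 h and the ATRi+shTIM list, 147 were in the ATRi+APH 18 h list alone, 30 in the ATRi+shTIM list alone and 37 in the DMSO list alone. Among the 32 loci in at least 4 lists, those with the highest fold in the ATRi+APH 18 h list lay near Gdf3, Gata4, Klf15 (2 loci), Ptgr2, Spon1 and Rnf145, and 3 further loci of the 10 highest lay in predicted genes that are not named here. Of the 3 loci of this kind that also held a DMSO peak, 1 lay in Ripor2 (chromosome 13, 24726124 to 24726321), 1 in Zc3h7a (chromosome 16, 11144026 to 11144310) and 1 in a predicted gene on chromosome 4.

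**Figure D3:**
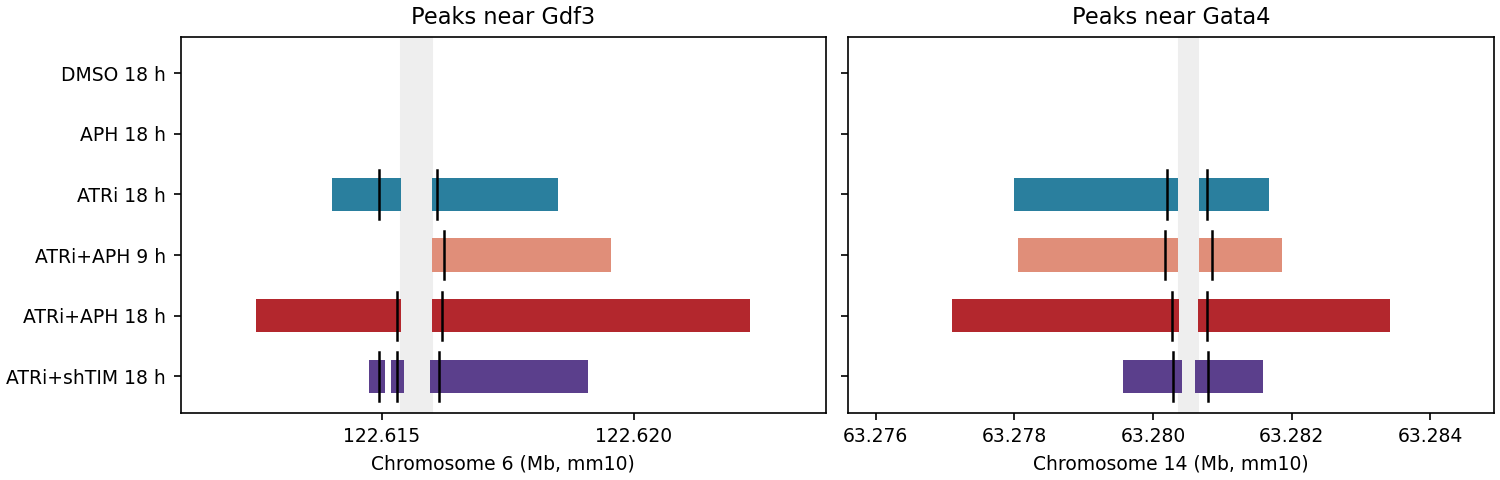
Bars show the peaks of each list (y axis) along chromosome 6 near Gdf3 and along chromosome 14 near Gata4 (x axis, position in Mb, mm10); black lines mark the summits given by the peak caller and the grey band is the gap between the adjoining ATRi+APH 18 h peaks. The gap near Gata4 lies between 63280371 and 63280652 and that near Gdf3 between 122615380 and 122616002, and the lists with ATR inhibitor that have a peak on a side of a gap end it close to these positions.

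Gene content was tested because long genes are known to break under replication stress. None of the peaks of the 5 lists tested lay in the 20 listed common fragile site genes, which include Fhit, Wwox and Immp2l. For ATRi+APH 18 h 3.81 peaks were expected there from random placement (two-sided permutation p = 0.0438, adjusted p = 0.307). Long neural genes held 1 ATRi+APH 18 h peak, in Ntm, a neuronal adhesion molecule (chromosome 9, 29483853 to 29484678, 8.62-fold), against 2.4 expected (adjusted permutation p = 1). Early replicating fragile site genes, replication stress response genes, fibroblast genes and histone genes held no peak of any list tested. At most 0.209 peaks were expected there from random placement, for early replicating fragile site genes in ATRi+APH 18 h, so these absences carry no information. Genes longer than 300 kb held 18 ATRi+APH 18 h peaks where 42.1 were expected (adjusted permutation p = 0.007) and 10 ATRi+shTIM peaks where 24.2 were expected (adjusted p = 0.0385). The ATRi+APH 18 h peaks lay in 17 such genes, among them Shisa6, Bcas3, Esr1, Camta1 and Dpyd. For ATRi+APH 9 h the count was 2 against 8.82 expected (adjusted permutation p = 0.142), for ATRi 2 against 7.48 (adjusted p = 0.271) and for DMSO 3 against 6.12 (adjusted p = 1). With peaks under 1 kb apart merged, 17 ATRi+APH 18 h sites were counted against 32 expected and 10 ATRi+shTIM sites against 19.1, and neither passed the test after adjustment (adjusted permutation p = 0.098 and 0.338).

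Over all annotated genes, the share of summits within genes did not differ detectably from random placement in any list. It was 45% for ATRi+APH 18 h (95% interval 39.5 to 50.5%) against 47.1% expected (adjusted permutation p = 0.7) and 47.8% for DMSO against 49% (adjusted p = 1). Counting protein-coding genes alone, shares were below random placement for ATRi+APH 18 h (29.4% against 39%, adjusted permutation p = 0.0096), ATRi+APH 9 h (23.1% against 40.5%, adjusted p = 0.02) and ATRi+shTIM (28.7% against 38.6%, adjusted p = 0.02). The ATRi list had 26.8% against 40% (adjusted permutation p = 0.154) and the DMSO list 32.6% against 41% (adjusted p = 0.619). After merging peaks under 1 kb apart the 3 shares were 33.9%, 26.3% and 34.2%, and none passed the test.

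**Figure D4:**
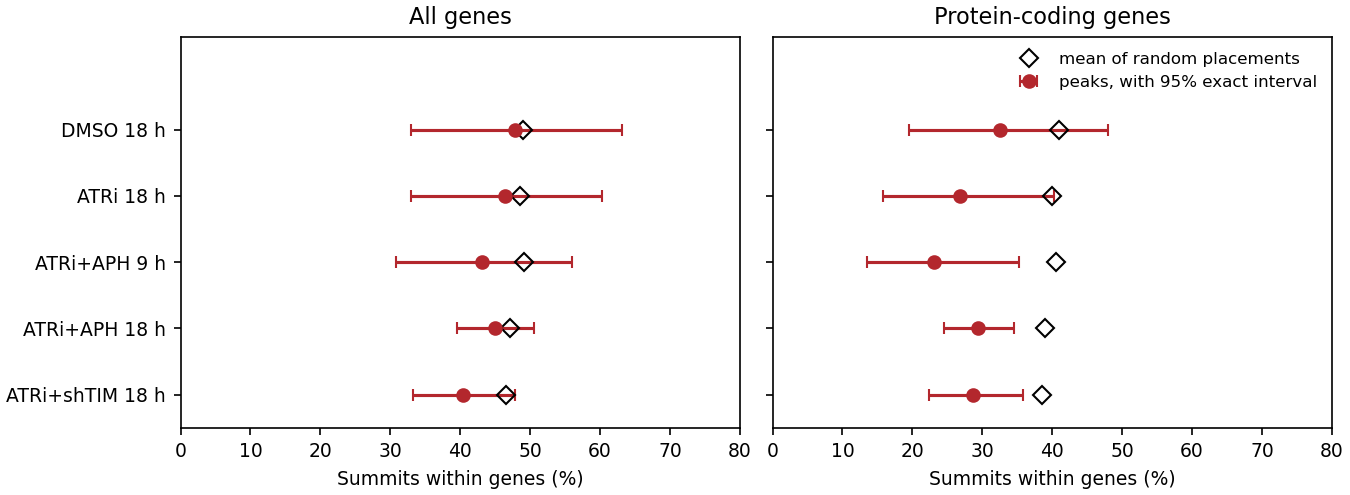
Filled points give the percentage of peak summits inside genes (x axis) for the lists with more than 1 peak (y axis), with 95% exact intervals, and open diamonds give the mean of 10000 random placements. For protein-coding genes the points for ATRi+APH 9 h, ATRi+APH 18 h and ATRi+shTIM, at 23.1%, 29.4% and 28.7%, lie below their diamonds by more than their intervals.

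Peaks were spread unevenly over chromosomes in all 5 lists tested (permutation p of the chi-square statistic between 0.0001, the smallest that the draws can give, and 0.0015). Chromosome X held 43 ATRi+APH 18 h peaks against 21.3 expected from its length (adjusted permutation p = 0.00667) and 34 ATRi+shTIM peaks against 12.3 (adjusted p = 0.00667). Of these, 23 and 20 stood between 170731958 and 170859471, in the pseudoautosomal region beyond Asmt, a gene of melatonin synthesis. Another 9 and 6 peaks stood between 135040271 and 135054732 on the same chromosome, and 9 and 8 near the start of chromosome 10, between 3109870 and 3117163. In the DMSO list all 11 peaks of chromosome 9 were those at its start, more than expected from its length (adjusted permutation p = 0.00667). With peaks under 1 Mb apart counted once, chromosome X held 9 ATRi+APH 18 h and 8 ATRi+shTIM sites and chromosome 9 held 1 DMSO site, and none of these differed detectably from expectation (adjusted permutation p = 1 for each); the uneven spread then passed the test for ATRi+APH 9 h alone (permutation p = 0.041).

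**Figure D5:**
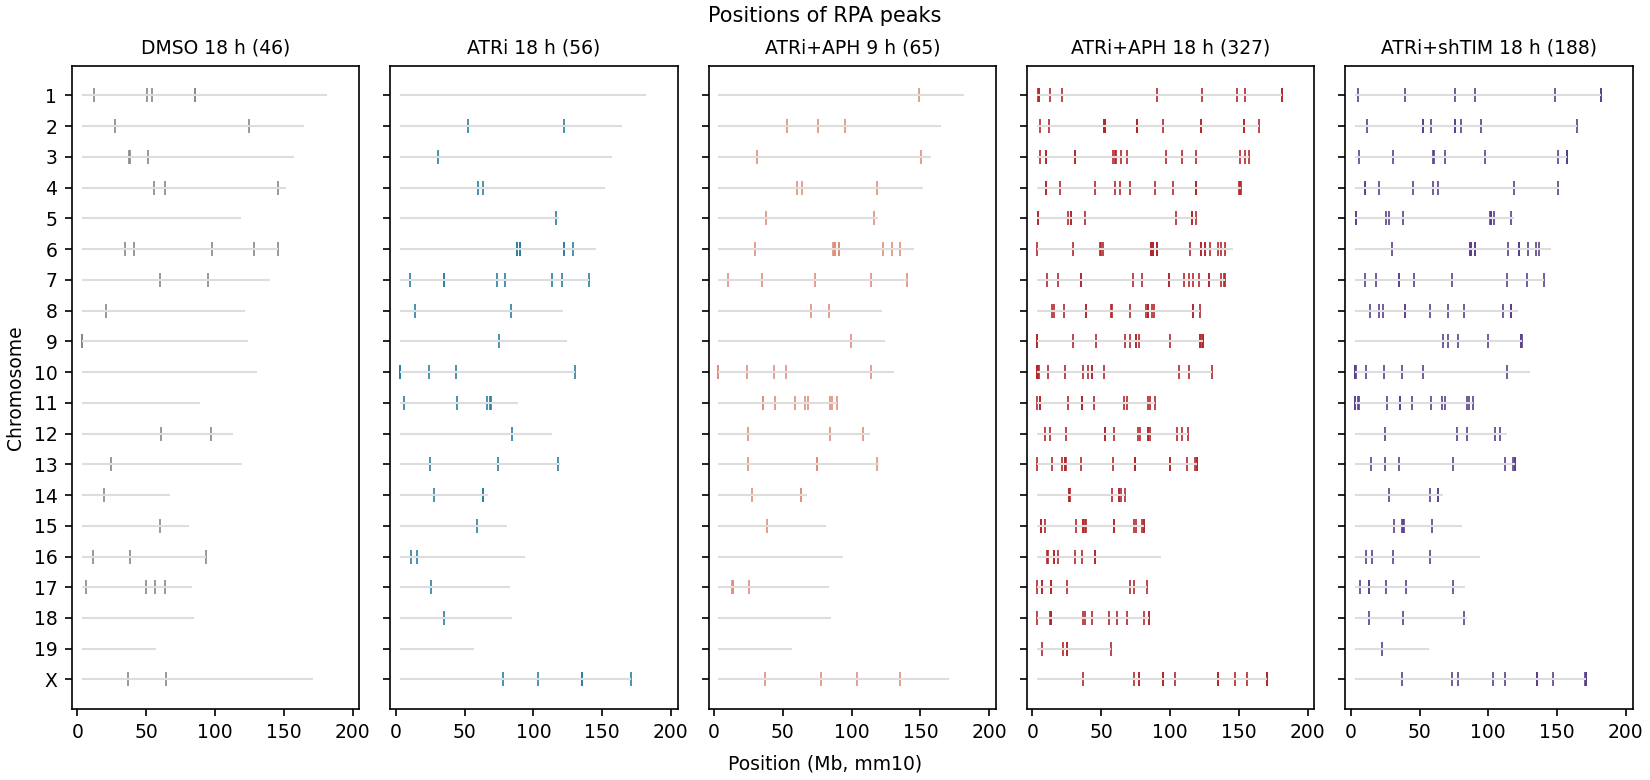
Each tick is a peak at its position in Mb (x axis, mm10) on its chromosome (y axis), for the 5 lists with more than 1 peak and with the number of peaks in brackets. The dense ticks at the far end of chromosome X comprise 23 ATRi+APH 18 h and 20 ATRi+shTIM peaks, and all 11 DMSO peaks of chromosome 9 stand at its start.

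Within the ATRi+APH 18 h list, peaks shared with other treatments were compared with the rest by the fold of the authors' peak caller. The other lists ended at different −log10 p, 29.9 for ATRi, 34 for ATRi+APH 9 h, 10.7 for ATRi+shTIM and 10 for DMSO. A list with a higher floor holds only stronger peaks, so floor and treatment cannot be told apart in the differences below. The 54 peaks shared with ATRi had a median of 16.2-fold (interquartile range 9.6 to 32.4) against 9.29-fold (6.42 to 12.3) for the others (permutation test of medians, adjusted p = 2.5e-05). Counting only peaks with at least 50% covered as shared, chosen after seeing the data, this difference of medians was 2.99 in place of 6.87 (adjusted permutation p = 0.00587), and that for ATRi+shTIM changed sign to −1.23 (adjusted p = 0.0575). The 65 peaks shared with ATRi+APH 9 h had a median of 14-fold against 9.44-fold (adjusted permutation p = 2.5e-05). The 166 peaks shared with ATRi+shTIM did not differ detectably from the rest, at 9.96-fold against 9.81-fold (adjusted permutation p = 0.889). The 9 peaks shared with DMSO had a lower median of 3.06-fold against 9.97-fold (permutation test, adjusted p = 0.019). In all, 8 ATRi+APH 18 h peaks stood at the start of chromosome 9 with folds of 2.56 to 3.33. Most of the 9 shared peaks were among them, so the test counts a cluster as independent peaks.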

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

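The tests at tRNA genes and at the end of chromosome X were chosen only after the peaks had been seen. The comparison with equally weak peaks was set after the tRNA peaks were found but before its own outcome was seen. The absence of tRNA gene peaks from the ATRi+shTIM list was known by then, which left that comparison little room to come out otherwise. Differences in overlap share were planned, apart from the common −log10 p of at least 34.

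Peaks at tRNA genes stood in the lists of ATRi and ATRi+APH at 18 h, and this differed between groups for ATRi against ATRi+shTIM. Of 56 ATRi peaks, 4 lay within 1 kb of a tRNA gene (7.14%, exact 95% interval 1.98 to 17.3%), as did 7 of 327 ATRi+APH 18 h peaks (2.14%), against 0.0219 and 0.118 expected from random placement (permutation p = 0.0002 each, the smallest possible; adjusted p = 0.002 over 20 tests of tRNA, rRNA, snRNA and snoRNA genes). They included n-TRtcg5 inside Polg, with 13.3-fold in ATRi and 14.8-fold in ATRi+APH 18 h, n-TLtag1 (chromosome 7, 120834963 to 120835807, 11.5-fold in ATRi), and n-THgtg3 with n-THgtg5 (chromosome 2, 122377336 to 122378503, 8.09-fold in ATRi). The DMSO, ATRi+APH 9 h and ATRi+shTIM lists had 0 such peaks. Over 5 comparisons between lists, only ATRi against ATRi+shTIM passed (adjusted Fisher's exact p = 0.0127). ATRi+APH 18 h against ATRi+shTIM missed the threshold (Fisher's exact p = 0.0515 before adjustment).

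Weakness of these peaks as the reason for their absence from the ATRi+shTIM list is not settled. Their −log10 p in ATRi ran from 32.5 to 59.9, while the ATRi+shTIM list ended at 10.7, though read depth is unknown. Of 40 other ATRi peaks with no higher −log10 p, 34 were in the ATRi+shTIM list, so most ATRi peaks of this strength or less were found there. The comparison with 0 of the 4 (Fisher's exact p = 0.00155) cannot decide, since that absence is the pattern that drew attention. Timeless knockdown may lower RPA at tRNA genes, with an upper limit of 1.94% for the share in ATRi+shTIM. ATRi+APH 9 h, with unaltered Timeless, also had 0 of 65, so the absence was not confined to the list with knockdown. This cannot decide about Timeless, since treatment time differs as well. The 9 h list ended at a −log10 p of 34, above most ATRi+APH 18 h peaks at tRNA genes. The ATRi+APH 18 h peaks at n-TRtcg5 (54.9) and n-TLtag1 (34.5) lay above that floor. In ATRi the peaks at tRNA genes had a −log10 p of 59.9, 48.2, 41.4 and 32.5. The floor thus covers only some of these absences. The 9 h share did not differ detectably from that of ATRi+APH 18 h (Fisher's exact p = 0.606). Antibody lot cannot be told apart from treatment: the lists with a tRNA gene peak are the 2 that include a library made with 1 of the 3 antibody lots, with 11 of 383 peaks against 0 of 299 in the other lists of more than 1 peak (Fisher's exact p = 0.00326). Reads shared between near-identical tRNA gene copies stay open: the lower share in ATRi+shTIM than in ATRi (Fisher's exact p = 0.00255) is the difference that drew attention and so decides nothing about them.

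The end of chromosome X, in the pseudoautosomal region beyond Asmt, held 23 of 327 ATRi+APH 18 h peaks and 0 of 65 ATRi+APH 9 h peaks, a difference between time points (Fisher's exact p = 0.0201; 12 of 179 against 0 of 65 among peaks reaching the floor of the 9 h list, p = 0.0396), in a test that counts the clustered peaks as independent.

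The share of peaks overlapping the ATRi+APH 18 h list differed between ATRi+APH 9 h and ATRi+shTIM, at 98.5% and 83.5% (adjusted Fisher's exact p = 0.00211).

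It also differed between ATRi and ATRi+shTIM, at 96.4% and 83.5% (adjusted Fisher's exact p = 0.026). With the counted lists held to the same −log10 p of at least 34, and the ATRi+APH 18 h list kept whole, neither difference passed the test. The ATRi and ATRi+shTIM lists shared no antibody lot, so lot cannot be told apart from treatment in the difference between them.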

How the results depend on the processing

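Shifting whole lists, the common −log10 p of at least 34, the alternatives for gene lists, folds and protein-coding shares, and merging within 1 kb other than for peak counts were chosen only after the data had been seen. Across 51 results and 209 alternative values, 158 kept their direction and their side of the threshold, or stayed close to the main count; 30 were weaker, 4 stronger, 9 moved and 8 reversed, 5 of these in results that passed no test. Of the 158, 71 concern shares of a list overlapping another and say little about stability: each had the smallest possible permutation p, 0.0002, as random overlaps are rare. Shares moved, for DMSO in ATRi+APH 18 h from 19.6% to 60% with a −log10 q of at least 10, and for ATRi+shTIM in DMSO from 1.6% to 0.532% with at least 50% covered and to 4% at the common −log10 p.

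Fewer peaks pass a stricter threshold by construction. At or above the pooled median fold of 9.83, DMSO kept 0 peaks, APH 0, ATRi 23, ATRi+APH 18 h 164 and ATRi+shTIM 99. With a −log10 q of at least 10 DMSO kept 5. At a common −log10 p of at least 34 DMSO kept 0, ATRi+APH 18 h 179 and ATRi+shTIM 50.

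With a −log10 q of at least 10, overlap shares with the ATRi+APH 18 h list differed by −36.4 points for DMSO minus ATRi (adjusted Fisher's exact p = 0.153), −38.5 for DMSO minus ATRi+APH 9 h (0.121), −33.2 for DMSO minus ATRi+shTIM (0.169), 3.2 for ATRi minus ATRi+shTIM (0.993) and 5.23 for ATRi+APH 9 h minus ATRi+shTIM (0.426). At the common −log10 p the last 2 were −2.88, a reversal, and 0.462. Counting peaks within 1 kb as shared gave 8.66 for ATRi minus ATRi+shTIM (0.155). The stricter thresholds remove weak peaks; the cause of the weakening within 1 kb was not tested.

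Shares within all genes passed the test only with protein-coding genes alone, at 23.1% for ATRi+APH 9 h, 29.4% for ATRi+APH 18 h and 28.7% for ATRi+shTIM. These protein-coding shares no longer passed when whole lists were shifted (adjusted permutation p = 0.168, 0.217 and 0.312, at the same shares) or merged within 1 kb (26.3%, 33.9% and 34.2%). Without peaks overlapping DMSO the ATRi share, 22.6%, passed (0.0208); the cause was not tested. Merging within 1 kb put the shares within all genes above expectation for DMSO (51.2%) and ATRi (53.2%), a reversal with no call.

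Within the ATRi+APH 18 h list, counting as shared only peaks at least 50% covered lowered the median fold difference for ATRi from 6.87 to 2.99 (adjusted permutation p = 0.00587) and reversed that for ATRi+shTIM from 0.157 to −1.23 (0.0575). The difference for sharing with any other list, −0.13, was reversed to 0.0365 within 1 kb (0.988) and to 0.25 without peaks overlapping DMSO (0.869). The cause was not tested.

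In genes over 300 kb, merging within 1 kb left 17 ATRi+APH 18 h sites where 32 were expected and 10 ATRi+shTIM sites where 19.1 were, merging within 1 Mb 16 where 24.9 were and 9 where 16 were, and shifting 18 where 42.1 were and 10 where 24.1 were. Each stayed below expectation and none passed the test (adjusted permutation p from 0.098 to 0.812).

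Merging joins clusters, and the chi-square statistic of peaks per chromosome then lost its call in most lists. ATRi+APH 9 h still passed within 1 Mb (31, permutation p = 0.041) and within 1 kb (34.5, p = 0.0153), and DMSO within 1 kb (38, p = 0.0069). Where it did not pass, it was within 1 Mb 23.3 for DMSO, 22.9 for ATRi, 17.2 for ATRi+APH 18 h and 12.4 for ATRi+shTIM, and within 1 kb 29 for ATRi, 26.8 for ATRi+APH 18 h and 25.9 for ATRi+shTIM. Chromosome X held 9 ATRi+APH 18 h sites within 1 Mb, below expectation (reversed), and 25 within 1 kb; for ATRi+shTIM it held 8 and 19. Chromosome 9 held 1 DMSO site within 1 Mb, also reversed, and 8 within 1 kb.

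No paired analysis was possible because each list pools its replicates without their numbers, and no replicate was left out for the same reason. The alternatives for tandem and inverted repeats were not run for lack of sequence. With 0 DMSO peaks left, their overlap at the common −log10 p has no value. Unknown depth limits comparisons of peak numbers.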

Other observations

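The tests of facing summits against chance, of edges at gaps, of clusters, of aphidicolin, of gene density in lists other than ATRi+APH 18 h, of gene density together with clusters and of the fold of the chromosome 9 DMSO peaks were chosen only after the results had been seen; the test of gene density alone in ATRi+APH 18 h and the comparison of outer edges between 9 h and 18 h were set before their outcomes were seen. The definition of a facing pair, adjoining peaks of at least 500 bp under 1 kb apart, and the gene names in these paragraphs were also chosen after the values were seen.

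Strong sites often consisted of 2 adjoining broad peaks with a short gap between them. In the ATRi+APH 18 h list 23 such pairs had a median gap of 280 bp, and the summits stood at a median of 91.9% of the length of the left peak and 9.24% of that of the right peak, next to the gap. The pair near Gdf3 spanned 9810 bp, that near Gp9 7567 bp and that near Gata4 6307 bp. Other pairs lay near Rif1, which encodes a regulator of replication timing (chromosome 2, 52064701 to 52069220), and overlapped Myo5a (chromosome 9, 75081230 to 75084859) and Pag1 (chromosome 3, 9801689 to 9804481). Both summits faced the gap in 4 of 4 ATRi pairs, 3 of 4 ATRi+APH 9 h pairs and 4 of 7 ATRi+shTIM pairs, and DMSO had 0 pairs.

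A flat enriched stretch divided by the peak caller is argued against, since 78.3% of the ATRi+APH 18 h pairs faced the gap (18 of 23, exact 95% interval 56.3 to 92.5%), and 16 of the 19 pairs that share no peak with another pair did (84.2%, 60.4 to 96.6%), where 25% is the chance share. Reads not placed on the sequence inside the gap are a candidate explanation of the inner edges, which stood close together where they were compared. Inner edges moved by medians of 8, 8 and 36 bp between ATRi+APH 18 h and the ATRi, ATRi+APH 9 h and ATRi+shTIM lists. Outer edges moved by 1228, 573 and 1360 bp (largest exact sign-flip p = 0.0022). Peaks of the other lists that reached across a gap into both peaks of a pair were left out, and gaps were under 1 kb. Inner edges thus had less room to move than outer edges by the way they were chosen, so the sign-flip test cannot decide. Between 9 h and 18 h the outer edges lay farther out at 18 h in 12 of 13 shared pairs (92.3%, exact 95% interval 64 to 99.8%). Pairs were chosen for peaks of at least 500 bp in the ATRi+APH 18 h list, with no such width asked of the other lists. That choice by itself favours outer edges farther out in ATRi+APH 18 h. It cannot be told apart from longer treatment or from the larger pool of 3 ChIP libraries at 18 h, since read depth is unknown. The outer edges also lay farther out in ATRi+APH 18 h than in ATRi, treated for the same time, in 11 of 11 pairs. Against ATRi+shTIM they did so in 10 of 14 (71.4%, exact 95% interval 41.9 to 91.6%). The choice of pairs by width in ATRi+APH 18 h applies to these comparisons too, so they do not show a widening by treatment. In the comparisons with ATRi+APH 9 h and ATRi+shTIM some pairs share a peak, so an outer edge of a pair can face the next gap. The edge tests and intervals count such pairs as independent.

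Genes over 300 kb held fewer ATRi+APH 18 h and ATRi+shTIM peaks than random placement gave. Sites merged within 1 kb had more protein-coding genes within 500 kb than random positions: 11.1 against 8.32 in ATRi+APH 18 h (permutation p = 0.0002), 11.3 against 8.5 in ATRi+shTIM (p = 0.0012), 14.3 against 9.14 in ATRi (p = 0.0024) and 14.2 against 9.14 in ATRi+APH 9 h (p = 0.0012). For DMSO the means were 7.6 and 8.36 (permutation p = 0.611), and the difference between lists was not tested.

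Gene density alone as the whole cause for ATRi+APH 18 h missed the criterion set beforehand. Of the sites, 17 lay in long genes where positions matched in gene number gave a mean of 26.9 (permutation p = 0.0336). These draws treat clustered sites as independent, which can make the p too small, so this test cannot decide against gene density. For ATRi+shTIM gene density stays open as well, with 10 sites against a matched mean of 15.5 (permutation p = 0.146). For ATRi+APH 9 h and ATRi the matched permutation test gave p = 0.477 and 0.593. Aphidicolin as the whole cause stays open. The ATRi+shTIM list, made without it, showed a shortage with peaks counted singly (permutation p = 0.0022). That shortage did not pass with sites merged within 1 Mb (permutation p = 0.0696), so it cannot decide. Clusters stay open (permutation p = 0.0602 for ATRi+APH 18 h merged within 1 Mb). Gene density together with clusters, considered only after the first test came out against density alone, may account for the ATRi+APH 18 h shortage: 191 sites merged within 1 Mb gave 16 in long genes against a matched mean of 18.3 (permutation p = 0.64), a p that does not show equality.

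At the start of chromosome 9 the 11 DMSO peaks had a lower median fold than the other 35, 2.19 against 5.98 (permutation p = 2e-05), with a higher median −log10 p, 16.6 against 11, and they made up 7 of the 10 highest −log10 p of the list. At the start of chromosome 10, ATRi had 6 peaks, ATRi+APH 9 h 2, ATRi+APH 18 h 9 and ATRi+shTIM 8 between 3109870 and 3117163, and DMSO had 0. Distances to ends were measured from 3 Mb, the first assembled position, and from the last annotated or listed base, not from the ends of the chromosomes themselves. Within 1 Mb of either position lay 11 of 46 DMSO peaks against 0.711 expected, 8 ATRi peaks against 0.84, 50 ATRi+APH 18 h peaks against 5.11 and 37 ATRi+shTIM peaks against 2.79 (permutation p = 0.0002 each), and 2 ATRi+APH 9 h peaks against 0.986 (p = 0.52). Those near the 3 Mb position were 11 for DMSO, 6 for ATRi, 22 for ATRi+APH 18 h, 10 for ATRi+shTIM and 2 for ATRi+APH 9 h. All 11 of DMSO stood at the start of chromosome 9, and 23 of ATRi+APH 18 h and 20 of ATRi+shTIM at the end of chromosome X, so these peaks are not independent.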
